A study of Mus musculus with 6 samples.

How the data were processed

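RNA was measured in 6 libraries of the mouse leukaemia cell line MLL-ENL-ERtm, 3 with a short hairpin RNA against Tet1 (shTet1) and 3 with a non-specific hairpin (shNS). Per the labels' protocols, polyadenylated RNA was isolated from total RNA and made into directional libraries, which keep the strand of each transcript. Groups and replicate numbers were taken from the sample titles, because the free-text descriptions carry 1 replicate number for every shNS library and another for every shTet1 library. The genome build was GRCm38, per the submitters' processing notes. The aligner, the read counter and the authors' test are not given in the sources used here.

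The authors deposited 1 table of 13839 genes with 6 columns of values, 1 for each library, that were taken as FPKM, reads scaled by gene length and library size; no header names the unit, which was inferred from the values. The deposited mean signal per group is, by its values, the mean of reads divided by a size factor per library. The deposited fold change (a ratio), its log2 value, the p-value and the adjusted p-value are the authors' own, per the file headers, and were used only where the authors' deposited table is named. The lowest mean in the table was 4.00 reads per size factor, and no mitochondrially encoded gene was present, so genes below that level were not analysed here. All 6 columns with values per library matched a title. There were 22 symbols that a spreadsheet had turned into dates and 12 blank symbols, and all were resolved by gene ID. Positions came from the RefSeq annotation of GRCm38 (GRCm38.p6), in which 13798 of the gene IDs were found.

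Dividing each gene's FPKM by what 1 read is worth gave whole reads for 100.0% of the values within a tolerance of 0.001 read, with a largest deviation of 7.2e-05. The recovered totals were 18592139, 16863077 and 16884517 reads for shNS replicates 1, 2 and 3 and 18060453, 17809219 and 15873632 for shTet1 replicates 1, 2 and 3. The 10 genes with the most reads took 5.16, 5.33 and 5.17% of the reads in shNS and 6.96, 7.22 and 6.43% in shTet1. There were 83 genes whose reads in every library equalled those of another gene. Across genes, the constant that links FPKM and reads had a Spearman correlation of 0.78 with exonic length. Chi-square per degree of freedom between replicates of a group lay between 4.64 and 38.09, so no library was a copy of another.

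The design chosen before the data were examined foresaw raw counts, with limma on log2 values as the fallback for normalized values. Since the table holds FPKM, the fallback was used: limma with an intensity trend on log2(FPKM + 1), for genes with at least 1 FPKM in at least 3 libraries, with Benjamini-Hochberg adjusted p under 0.05, two-sided, and group as the sole term. Fold changes are therefore on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Errors of levels are SD over the 3 libraries of a group, and errors of fold changes are standard errors from limma. limma-voom was run on the recovered reads, for genes with at least 10 reads in at least 3 libraries, as an alternative.

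There were 34 gene lists fixed before the data were examined, of which 31 had at least 3 tested genes and were tested with camera in limma, at a preset correlation of 0.01 between genes, and adjusted over the lists. Members were counted as past adjusted p 0.05 over all genes tested and adjusted over the list alone. The camera test was repeated with the correlation estimated from the data, and fry was run as a further alternative. The latter asks whether a list's genes move one way and does not compare them with other genes. Named genes followed a rule fixed at the same time: the 12 largest rises and 12 largest falls past adjusted p 0.05 with no overlap between groups and a mean of at least 5 FPKM, leaving out predicted or unnamed symbols; up to 4 members of each list with the smallest p (the 2 most expressed where none passed); and Tet1, Tet2, Tet3, Hoxa9, Meis1, Pbx3, Myc and Kit. Where 5 or fewer members of a list moved one way, those outside the rule were also named, chosen after their values were seen. Some genes that this rule takes are not reported here.

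A fit with the replicate number as a block was planned before the data were examined. Deviations of same-numbered libraries from their group means had correlations across genes of 0.61, 0.36 and 0.21 for replicates 1, 2 and 3; genes are not independent replicates. Since each was above 0.1, the numbers were taken as pairs. Differently numbered libraries had correlations from −0.52 to 0.34. Those of shNS replicate 2 with shTet1 replicate 3 (0.34) and shNS replicate 3 with shTet1 replicate 2 (0.14) were also above 0.1. As pairs, only the replicate 1 libraries were therefore set apart from the others by their number. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The other alternatives were median-of-ratios scaling, no filter, a filter of 5 FPKM, a pseudocount of 0.1 with and without the filter, stricter thresholds, and each library left out in turn. Fits without both replicate 1 libraries, without the genes of identical reads, and limma-voom with the block were added after the data had been examined.

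The limma steps were tested on simulated reads made from the shNS means and the read totals of the libraries. All genes had the same spread between replicates (dispersion 0.00383). A random 67, 67 and 66 genes were changed 1.5-, 2- and 4-fold, as many up as down. limma on log2(FPKM + 1) found 91, 100 and 100% of the genes changed 1.5-, 2- and 4-fold among 11567 genes with 19 false calls (8.9% of its calls), and limma-voom 94, 100 and 100% among 13153 genes with 7 (3.4%). The share for limma on log2(FPKM + 1) was above the 5% that the threshold is meant to hold. The real comparison had many more changed genes, uneven in direction, and replicates that differed in spread, so these shares may not hold for it. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.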

Results

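Gene expression was measured by RNA sequencing in MLL-ENL-ERtm cells, a mouse leukaemia line that carries the MLL-ENL fusion and that the labels class as acute monocytic leukaemia. The cells had received a retroviral short hairpin RNA against Tet1 (shTet1, 3 libraries) or a non-specific hairpin (shNS, 3 libraries). Reads were single-end and 51 bp long, and between 15873632 and 18592139 reads per library fell on the genes of the deposited table. The comparison asks which transcripts differ when Tet1, an enzyme that oxidises 5-methylcytosine in DNA, is knocked down in these cells.

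Tet1 (gene ID 52463, chromosome 10, 62804570 to 62887469, GRCm38) stood at 0.489, 0.392 and 0.446 FPKM in shNS replicates 1, 2 and 3 and at 0.0982, 0.155 and 0.139 FPKM in shTet1 replicates 1, 2 and 3. The means were 0.442 ± 0.0487 and 0.131 ± 0.0294 FPKM (SD, n = 3 each), so that shTet1 held 29.6% of the shNS level. These levels rest on 128, 93 and 106 reads against 25, 39 and 31 reads. Tet1 lay below the expression filter in every library, and an exact two-sided permutation test of its 6 values gave p = 0.1, the smallest that 3 against 3 allows. With limma-voom on the recovered reads its log2 change was −1.64 (SE 0.23, adjusted p = 0.000535), and in the authors' deposited table it was −1.62 (adjusted p 1.88e-09). Its paralog Tet2 rose from 8.97 ± 0.318 to 15.1 ± 0.533 FPKM (log2 change 0.69, SE 0.08, limma adjusted p = 0.000345). Tet3 was at 13.1 ± 2.41 and 12.7 ± 2.21 FPKM, with a log2 change of −0.04 that became 0.09 with median-of-ratios scaling (limma adjusted p 0.848 and 0.689).

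**Figure D1:**
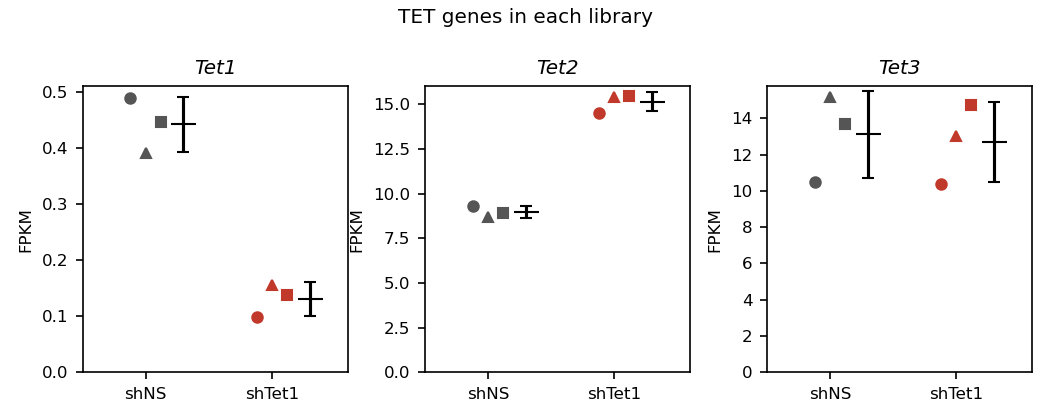
Expression of Tet1, Tet2 and Tet3 in FPKM (vertical axes) in each shNS and shTet1 library, with circle, triangle and square for replicates 1, 2 and 3, a cross for the mean and a bar for the SD. The shTet1 libraries lie between 0.0982 and 0.155 FPKM for Tet1, all below the shNS libraries, and all above them for Tet2.

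In the knockdown libraries, 20 of 21 monocyte and macrophage genes rose and 11 of 14 stem and progenitor cell genes fell (limma camera adjusted p 4.24e-14 and 0.000272, both with adjusted p = 0.431 with an estimated correlation). Saa3 (gene ID 20210, chromosome 7, 46711998 to 46719615), an acute-phase protein made by activated macrophages, rose from 30.6 ± 2.66 to 892 ± 528 FPKM (SD, n = 3), although the shTet1 libraries spread from 1277 and 1107 down to 290.5 FPKM. Csf1r (gene ID 12978, chromosome 18, 61105572 to 61131139), the receptor for the macrophage growth factor CSF1, rose from 25.7 ± 3.45 to 125 ± 26.6 FPKM. Mycn (gene ID 18109, chromosome 12, 12936093 to 12941836), a MYC family transcription factor, fell from 18.6 ± 1.92 to 2.32 ± 0.173 FPKM. Hexa (gene ID 15211, chromosome 9, 59539540 to 59565109), which encodes the alpha subunit of lysosomal beta-hexosaminidase, fell from 13.5 ± 1.94 to 0.614 ± 0.403 FPKM.

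Of 11646 genes tested with limma, 2254 were higher and 3925 lower in shTet1 at adjusted p under 0.05, a split of 36.5 to 63.5%. The median log2 change of all tested genes was −0.13, and median-of-ratios scaling moved it to −0.01 and the counts to 2914 higher and 2728 lower (51.6 to 48.4%). All 2254 genes higher in the deposited FPKM were also higher after that scaling, and 2728 of the lower genes were also lower. Medians of gene lists are therefore given with their distance from the all-gene median. Counts of list members that rose or fell are to be read against the 2254 and 3925 of 11646 genes. A list of any genes would hold many such calls. The authors' deposited table called 3275 genes higher and 3058 lower, of which 2247 and 2772 were called in the same direction here and 0 in the opposite one. The groups did not overlap for 7192 genes (61.8%, where chance gives 10%). On the first principal component, which held 79.5% of the variance, the shTet1 libraries scored 35.0, 35.2 and 22.7 and the shNS libraries −30.2, −29.5 and −33.2. There shTet1 replicate 3 lay nearer to shNS than the other shTet1 libraries. Its mean log2 level of the MYC target list was 5.53, against 4.88 and 5.20 in shTet1 replicates 1 and 2. Lists differed in this, as its mean of the progenitor list was the lowest (2.94 against 3.25 and 3.06).

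Among the 12 largest rises, Saa3 changed by 4.56 on the log2 scale (SE 0.49, limma adjusted p = 0.000283). Gpnmb (gene ID 93695, chromosome 6, 49036518 to 49058182), a glycoprotein of macrophages, followed at 3.07 (SE 0.19, limma adjusted p = 5.05e-05), from 3.70 ± 0.698 to 39.2 ± 10.2 FPKM. The galectin gene Lgals3 (gene ID 16854, chromosome 14, 47373860 to 47386167) changed by 3.02, from 3.24 ± 0.301 to 34.0 ± 8.16 FPKM. The membrane protein genes Ms4a6c, Ms4a6d and Ms4a6b rose by 2.73, 2.57 and 2.24, and the lectin receptor genes Clec4a1 and Clec4a3 by 2.72 and 2.65. Both are clusters of similar neighbouring genes, between which reads can be shared. Ifi202b (2.33), Eepd1 (2.32), the ribonuclease gene Rnase2a (2.27) and Csf1r (2.23) completed the group. Among the 12 largest falls, Hexa changed by −3.18 (SE 0.18, limma adjusted p = 4.45e-05) and the matrix proteoglycan gene Vcan (gene ID 13003, chromosome 13, 89655309 to 89743027) by −2.85, from 10.3 ± 1.73 to 0.566 ± 0.0926 FPKM. Vcan was below the filter, and so not tested, whenever an shNS library was left out. The GTPase gene Gem fell from 31.5 ± 2.87 to 3.59 ± 0.0627 FPKM (−2.82) and the lactoferrin gene Ltf from 107 ± 24.5 to 18.0 ± 2.44 FPKM (−2.49). The others were Mycn (−2.56), Myl10 (−2.52), Olfm4 (−2.44), Clnk (−2.32), the adhesion receptor gene Gpr56 (−2.18), Stfa2 (−2.13, one of several near-identical stefin genes), Serpina3g (−2.12) and the granzyme gene Gzmb (−2.10).

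**Figure D2:**
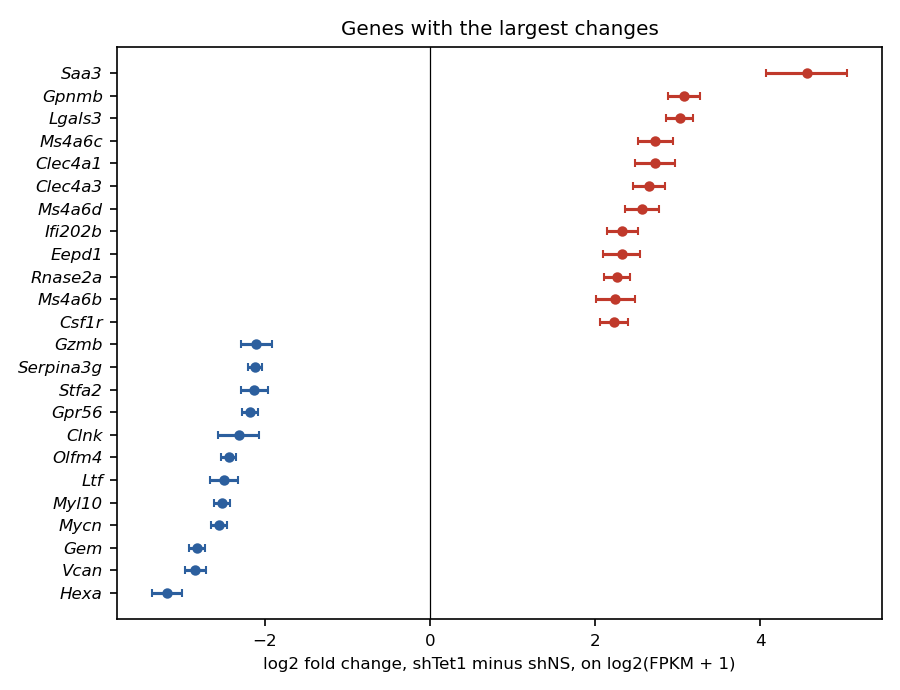
Log2 change from shNS to shTet1 (horizontal axis, log2(FPKM + 1) scale) of the 12 largest rises and 12 largest falls, with points for the limma estimate and bars for its SE. Rises run from 2.23 for Csf1r to 4.56 for Saa3 and falls from −2.10 for Gzmb to −3.18 for Hexa.

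Of 21 monocyte and macrophage genes tested, 20 rose and 1 fell, also when adjusted over the list alone (median log2 change 1.6, or 1.73 relative to all genes; limma camera adjusted p = 4.24e-14, and adjusted p = 0.431 with an estimated correlation). Mpeg1, the pore-forming perforin-2 of macrophages, rose from 121 ± 13 to 507 ± 69.0 FPKM (log2 change 2.05). The mannose receptor gene Mrc1 rose from 15.1 ± 1.6 to 59.0 ± 2.70 FPKM (1.90). Emr1, which encodes the macrophage antigen F4/80, rose from 26.1 ± 1.82 to 81.3 ± 6.19 FPKM (1.6) and the scavenger receptor gene Msr1 by 1.56. The member that fell was Apoe, a lipid carrier (−0.61), whose call ended with median-of-ratios scaling and with limma-voom (adjusted p 0.0941), and without shNS replicate 2, shNS replicate 3, shTet1 replicate 1 or shTet1 replicate 2. Apoe and the other list members named as exceptions to their list were chosen after their values were seen. Of 11 dendritic cell and MHC class II genes, 4 rose and 1 fell, with no other count when adjusted over the list alone (median 0.16, or 0.29 relative to all genes). The list was not called (limma camera adjusted p = 0.0598), but was with the replicate block (0.0324, and adjusted p = 0.687 with an estimated correlation), without shNS replicate 2 (0.0301), without shTet1 replicate 1 (0.0255), without both replicate 1 libraries (0.0461) and without the filter (0.0443). The antigen presentation genes H2-Aa, Cd74, H2-Eb1 and H2-DMb1 changed by 0.68, 0.74, 0.43 and 0.38, and the receptor gene Flt3 by −1.41. The count of rises was 2 without shNS replicate 1, shNS replicate 3 or shTet1 replicate 2.

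Of 14 stem and progenitor cell genes tested, 11 fell and 1 rose, also when adjusted over the list alone (median −1.53, or −1.40 relative to all genes; limma camera adjusted p = 0.000272, and adjusted p = 0.431 with an estimated correlation). The transcription factor genes Gata2, Mecom and Sox4 fell with Mycn. Gata2 changed from 26.7 ± 2.74 to 6.93 ± 0.618 FPKM (−1.80), Sox4 from 41.9 ± 0.341 to 13 ± 1.65 FPKM (−1.62) and Mecom by −1.64. The surface antigen gene Ly6a rose (1.14), and with the replicate block 2 members were higher. The growth factor receptor gene Kit was at 22.1 ± 2.30 and 19.5 ± 1.18 FPKM (log2 change −0.17, limma adjusted p = 0.183). Of 24 target genes of rearranged MLL, 12 fell and 4 rose (14 and 4 adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.21). The homeobox gene Meis1 fell from 17.0 ± 0.623 to 8.20 ± 0.737 FPKM (−0.97, SE 0.09, limma adjusted p = 0.000161) and the anti-apoptotic gene Bcl2 from 14.4 ± 0.621 to 4.31 ± 0.359 FPKM (−1.54). Zeb2 (1.39), Hoxa11 (0.88) and Igf2bp3 (0.85) were among those that rose. Hoxa9 fell from 17.6 ± 0.930 to 14 ± 1.68 FPKM (−0.31, SE 0.10, limma adjusted p = 0.0311), a call that ended with median-of-ratios scaling (0.139), with limma-voom (0.119) and without shNS replicate 1 (0.0862), shNS replicate 3 (0.106), shTet1 replicate 1 (0.0662) or shTet1 replicate 2 (0.101). Pbx3 had a log2 change of −0.07 (limma adjusted p = 0.523) that became 0.06 with median-of-ratios scaling.

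The neutrophil lists went both ways, and they hold other genes besides those of granules, so this is not a split of granule genes alone. Of 18 genes of the primary granule list, 3 rose and 9 fell, also adjusted over the list alone (limma camera adjusted p = 0.508). Haptoglobin (Hp, from 241 ± 36.9 to 779 ± 57.5 FPKM, 1.70), Igsf6 (1.30) and the elastase gene Elane (0.59) rose, and Nkg7 (−1.48) and Rab44 (−0.75) were among those that fell. Of 21 secondary granule and maturation genes, 10 rose and 8 fell, also adjusted over the list alone. The median was −0.05 (0.08 relative to all genes), the mean 0.09 and the camera direction higher (limma adjusted p = 0.29). Cybb, the catalytic subunit of the phagocyte oxidase, rose from 103 ± 1.99 to 455 ± 78.8 FPKM (2.11) and the integrin gene Itgam by 1.19, while Ltf and Padi4 (−1.24) fell.

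Of 6 mast cell and basophil genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone; median −0.97, or −0.83 relative to all genes; limma camera adjusted p = 0.0332, and adjusted p = 0.633 with an estimated correlation). The protease genes Mcpt8 and Cpa3 changed by −1.68 and −1.15, Gzmb by −2.10 and the IgE receptor gene Fcer1a by −0.78. The call ended without shTet1 replicate 3 (0.0858) and with the 5 FPKM filter (0.0509), and Fcer1a was not past the test without shTet1 replicate 2 (limma adjusted p 0.0543). Of 5 eosinophil genes, 3 rose and 1 fell (limma camera adjusted p = 0.0744; the same counts adjusted over the list alone). The ribonuclease genes Ear2 (1.96), Ear1 (1.74) and Ear6 (0.93), which are near copies of each other, rose, and Siglec5 (−0.84) fell. The reads of Ear6 equalled those of another gene in every library, so its rise cannot be assigned to Ear6 alone. Ear6, like Treml1 of the platelet genes, was below the filter whenever an shTet1 library was left out. Of 10 megakaryocyte and platelet genes, 3 rose and 4 fell, also adjusted over the list alone (limma camera adjusted p = 0.941). Itga2b (−1.88), Gp9 (−1.33), Itgb3 (−0.91) and Ppbp (−0.74) fell, and Treml1 (1.13), Vwf (0.89) and Plek (0.64) rose. The median was 0.02 (0.15 relative to all genes), the mean −0.20, the camera direction higher and the fry direction lower.

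Of 4 T and NK cell genes, 1 rose (Il7r, 1.64) and 2 fell (Lck, −1.24, and Cd247, −0.37), also adjusted over the list alone. The median was −0.09 (0.04 relative to all genes), the mean 0.06 and the limma camera adjusted p 0.756. Cd247 did not pass with median-of-ratios scaling (limma adjusted p 0.0533) or without shTet1 replicate 2 (0.0736) or shNS replicates 1, 2 and 3 in turn (0.0762, 0.0513 and 0.0503). Lck was below the filter whenever an shNS library was left out. Of 4 stromal genes, 2 rose and 1 fell (limma camera adjusted p = 0.297; the same counts adjusted over the list alone). Fibronectin (Fn1, from 19.0 ± 1.98 to 78.3 ± 17.3 FPKM, 1.97) and Acta2 (0.36) rose, and Thy1 (−1.35) fell. Acta2 was not past the test without shNS replicate 3 (0.0809) or shTet1 replicate 2 (0.0698). The erythroid and B cell lists had 2 tested genes each and no list test: Hemgn (−1.64) and the transferrin receptor gene Tfrc (−1.03) fell, Cd22 (1.10) rose and Cd79b (−0.59) fell. Cd22 was below the filter whenever an shTet1 library was left out.

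**Figure D3:**
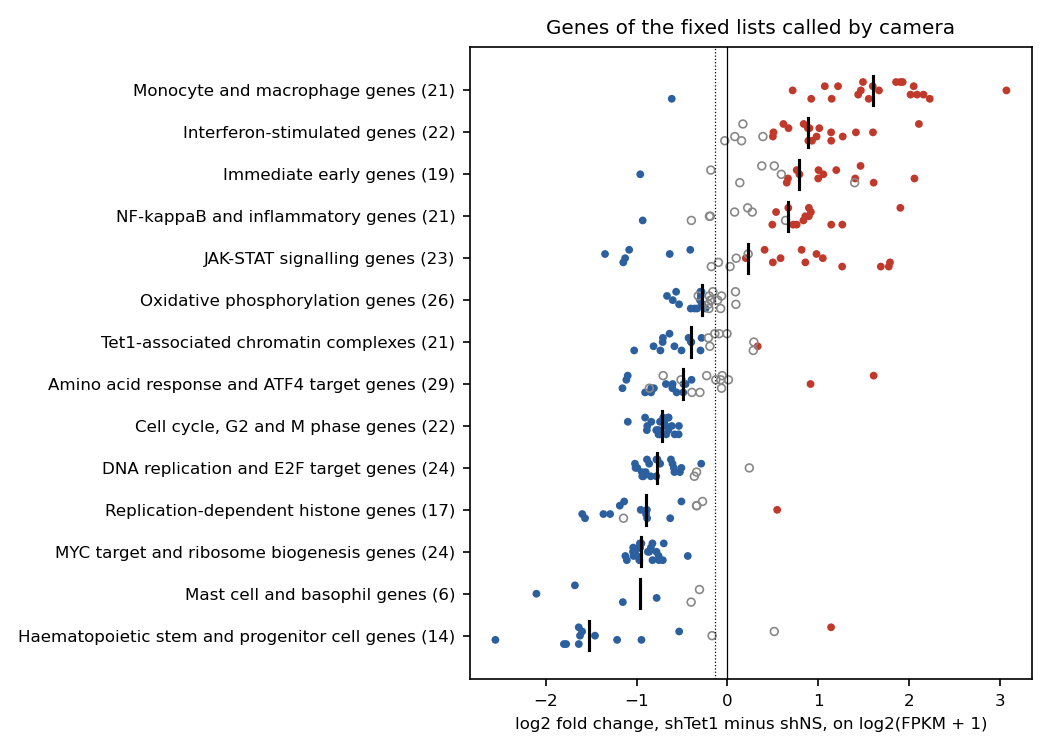
Log2 change from shNS to shTet1 (horizontal axis, log2(FPKM + 1) scale) of every tested gene in the 14 called lists, filled red or blue where higher or lower past limma adjusted p 0.05 and open where not, with a bar for the list median, a dotted line for the all-gene median of −0.13 and the number of tested genes beside each list. The monocyte and macrophage genes have the highest median of these lists (1.6) and the stem and progenitor cell genes the lowest (−1.53).

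Genes of cell division were lower in the knockdown. All 22 genes of the G2 and M phases fell, also adjusted over the list alone (median −0.72, or −0.59 relative to all genes; limma camera adjusted p = 8.96e-06, and adjusted p = 0.614 with an estimated correlation). Cyclin B1 (Ccnb1) fell from 61.6 ± 2.43 to 33.0 ± 3.33 FPKM (−0.89), topoisomerase 2 alpha (Top2a) from 124 ± 10.3 to 69.0 ± 6.85 FPKM (−0.84), Cdk1 by −0.91 and the kinesin gene Kif11 by −0.74. Of 24 DNA replication genes, 21 fell and 0 rose (22 and 0 adjusted over the list alone; median −0.78, or −0.64 relative to all genes; limma camera adjusted p = 2.49e-05, and adjusted p = 0.614 with an estimated correlation). The replicative helicase genes Mcm7, Mcm2 and Mcm3 changed by −0.99, −1.01 and −1.02, and the ribonucleotide reductase gene Rrm1 by −0.93. Replication-dependent histone genes, a list fixed for RNA quality, have transcripts that mostly lack a poly(A) tail and are near copies of each other. They had 12 falls and 1 rise among 17, also adjusted over the list alone (median −0.90, or −0.76 relative to all genes; limma camera adjusted p = 0.00813, and adjusted p = 0.633 with an estimated correlation). The list was also lower in replicate 1 than in replicates 2 and 3 (median −0.38 in shNS and −0.57 in shTet1). Each replicate number occurs once in each group, so that shift does not account for the fall in the knockdown. Without both replicate 1 libraries, 16 members fell (limma camera adjusted p 3.12e-05). The G2 and M phase list did not move with the histone list in replicate 1 (median 0.10 in shNS and −0.04 in shTet1). The fall of the histone list in the knockdown can therefore not be read as one of cell division alone. Hist1h3a, Hist1h3c, Hist1h2ac and Hist1h2ae changed by −1.57, −1.6, −0.90 and −0.89, and the linker histone gene Hist1h1c by 0.55, which was not past the test without shNS replicate 1, shNS replicate 3, shTet1 replicate 2 or shTet1 replicate 3.

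All 24 genes of the MYC target and ribosome biogenesis list fell, also adjusted over the list alone (median −0.95, or −0.82 relative to all genes; limma camera adjusted p = 8.96e-06, and adjusted p = 0.614 with an estimated correlation). Myc itself fell from 78.5 ± 4.78 to 42.3 ± 2.16 FPKM (−0.88, SE 0.08, limma adjusted p = 0.000161), the nucleolar protein genes Nop58 and Wdr12 by −1.04 and −0.98, and nucleophosmin (Npm1) from 929.8 ± 51.7 to 573 ± 51.3 FPKM (−0.70). Of 25 cytoplasmic ribosomal protein genes, 10 fell and 0 rose (6 and 0 adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.0601), but was with the replicate block (18 falls, 0.0145, and adjusted p = 0.736 with an estimated correlation), without shTet1 replicate 1 (19 falls, 0.0077), without both replicate 1 libraries (16 falls, 0.00836) and without shNS replicate 3 (4 falls, 0.0347). Rpl8 changed from 1463 ± 49.1 to 1082 ± 28.6 FPKM (−0.44) and Rpl3 by −0.39. Falls numbered 2 with median-of-ratios scaling or limma-voom, 3 without shNS replicate 1, shNS replicate 2 or shTet1 replicate 2, and 6 without shTet1 replicate 3.

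Inhibitors of the cell cycle and p53 targets had 5 rises and 5 falls among 22 genes, also adjusted over the list alone (limma camera adjusted p = 0.273). The death receptor gene Fas (1.31), Btg2 (1.22) and the CDK inhibitor genes Cdkn2d (0.61), Cdkn1a (0.40) and Cdkn2c (0.39) rose. Phlda3 (−0.75), Aen (−0.54), Bbc3 (−0.47), Sesn1 (−0.46) and Pmaip1 (−0.41) fell, and there were 3 falls with median-of-ratios scaling, without shNS replicate 3 or without shTet1 replicate 2. Of 13 genes of the BCL2 family, 7 rose and 3 fell, also adjusted over the list alone (limma camera adjusted p = 0.126, but 0.0343 without shTet1 replicate 1 and 0.0473 without both replicate 1 libraries; with all libraries, adjusted p = 0.614 with an estimated correlation). The anti-apoptotic Mcl1 rose from 109 ± 10.2 to 235 ± 39.7 FPKM (1.09), as did the pro-apoptotic Bmf (1.67) and Bcl2l11 (0.72), while Bcl2, Bcl2l1 (−0.60) and Bid (−0.53) fell. Of the list, 4 members rose without shTet1 replicate 2.

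Of 22 interferon-stimulated genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone; median 0.89, or 1.02 relative to all genes; limma camera adjusted p = 2.09e-08, and adjusted p = 0.563 with an estimated correlation). Oas1a and Oas2, which make the activator of RNase L, rose from 17.4 ± 0.929 to 35.5 ± 3.39 FPKM (0.98) and from 3.09 ± 0.0394 to 11.7 ± 3.06 FPKM (1.6). The GTPase gene Gbp2 changed by 1.14 and the RNA sensor gene Ifih1 by 0.93. With the 5 FPKM filter 13 members were tested and 11 rose.

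Inflammatory genes of the NF-kB list had 13 rises and 1 fall among 21, also adjusted over the list alone (median 0.67, or 0.80 relative to all genes; limma camera adjusted p = 0.000138, and adjusted p = 0.387 with an estimated correlation). The inflammasome gene Nlrp3 (1.27), the receptor antagonist gene Il1rn (1.14), Relb (0.90) and the chemokine gene Ccl9 (0.72) rose, and the cytokine gene Il6 fell (−0.93), with 2 falls under the replicate block. Of 23 JAK-STAT signalling genes, 12 rose and 6 fell, also adjusted over the list alone (median 0.23, or 0.36 relative to all genes; limma camera adjusted p = 0.0145, and adjusted p = 0.479 with an estimated correlation). The receptor subunit genes Il6st (from 18.0 ± 1.6 to 64.7 ± 1.81 FPKM, 1.79) and Il6ra (1.69) rose, as did Socs3 (1.78) and Stat6 (0.86). Of 19 immediate early genes, 12 rose and 1 fell, also adjusted over the list alone (median 0.79, or 0.93 relative to all genes; limma camera adjusted p = 8.15e-05, and adjusted p = 0.479 with an estimated correlation). The AP-1 genes Fosl2 and Junb rose by 1.47 and 1.00, Klf6 by 1.00 and Atf3 by 1.61, and the phosphatase gene Dusp2 fell (−0.96).

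Of 17 genes of the TET enzymes and DNA methylation machinery, 4 rose and 8 fell, also adjusted over the list alone (limma camera adjusted p = 0.455). The DNA methyltransferase gene Dnmt3b fell from 17.4 ± 1.23 to 5.37 ± 0.502 FPKM (−1.53). Of the isocitrate dehydrogenases, Idh1, which makes the TET cofactor 2-oxoglutarate in the cytosol, rose from 67.7 ± 7.65 to 169.9 ± 38.8 FPKM (1.30), and the mitochondrial Idh2 fell (−0.72). Tet2, Neil1 (0.35) and Mbd2 (0.29) were the other rises, of which there were 2 in all without shNS replicate 2 or shTet1 replicate 2. Of 21 genes of chromatin complexes linked to Tet1, 13 fell and 1 rose, also adjusted over the list alone (median −0.40, or −0.27 relative to all genes; limma camera adjusted p = 0.0326, and adjusted p = 0.431 with an estimated correlation). The H3K27 methyltransferase gene Ezh2 fell from 44.8 ± 1.69 to 25.1 ± 1.22 FPKM (−0.81), with Rbbp7 (−1.03), the Polycomb gene Bmi1 (−0.74) and Rbbp4 (−0.64), and the H3K27 demethylase gene Kdm6b rose (0.33). The call ended without shTet1 replicate 3 (0.0508), and 3 members rose with the replicate block and 2 without shTet1 replicate 3.

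Of 26 oxidative phosphorylation genes, 14 fell and 0 rose, also adjusted over the list alone (median −0.28, or −0.15 relative to all genes; limma camera adjusted p = 0.0307, and adjusted p = 0.633 with an estimated correlation). Ndufa4 (−0.66) and the ATP synthase gene Atp5b (−0.53, from 597 ± 3.68 to 415 ± 51.1 FPKM) were among them. That call ended with median-of-ratios scaling (4 falls, 0.0978), limma-voom (5 falls, 0.0897, or 0.0524 with the block) and without shTet1 replicate 2 (6 falls, 0.0649), and there were 9, 8 and 6 falls without shNS replicates 1, 2 and 3. Of 29 amino acid response genes, 16 fell and 2 rose, also adjusted over the list alone (median −0.49, or −0.35 relative to all genes; limma camera adjusted p = 0.0203, and adjusted p = 0.633 with an estimated correlation; 0.0674 with the 5 FPKM filter). The serine synthesis genes Phgdh, Psat1 and Psph fell, Phgdh from 149 ± 9.65 to 69.6 ± 12.8 FPKM (−1.10), Psat1 by −0.84 and Psph by −0.61, and the transcription factor genes Atf3 and Cebpb (0.92) rose, with 1 rise without shNS replicate 2 or shNS replicate 3.

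Of 21 glycolysis genes, 3 rose and 6 fell, also adjusted over the list alone, and 6 rose and 2 fell with median-of-ratios scaling (limma camera adjusted p = 0.418). The lactate exporter gene Slc16a3 rose from 7.68 ± 0.453 to 36.5 ± 4.53 FPKM (2.10), with Aldoc (1.65) and Pfkfb4 (0.65), and the glucose transporter gene Slc2a3 (−1.77) and Hk3 (−0.53) fell. Rises numbered 6 with the replicate block, and falls 3 without shNS replicate 2 or shNS replicate 3. Of 20 fatty acid oxidation and synthesis genes, 5 rose and 6 fell, also adjusted over the list alone (median −0.06, or 0.07 relative to all genes, camera direction higher, fry direction lower; limma camera adjusted p = 0.669). Pparg (0.74), Ppard (0.54), Cpt1a (0.41), Acadvl (0.31) and Acaa2 (0.22) rose, and Scd1 (−0.54) and Acaca (−0.51) fell. Rises numbered 8 with limma-voom and 3 without shNS replicate 2 or shNS replicate 3. Of 22 cholesterol biosynthesis genes, 10 fell and 1 rose (9 and 1 adjusted over the list alone; limma camera adjusted p = 0.29). Acat2 (−0.87) and Lss (−0.76) fell and Sc5d rose (0.62), with 3 rises under the replicate block or median-of-ratios scaling and 2 without shTet1 replicate 1.

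Of 18 heat shock and unfolded protein genes, 9 fell and 1 rose, also adjusted over the list alone (limma camera adjusted p = 0.0677, but 0.0448 without shNS replicate 3 and 0.0157 without shTet1 replicate 3, and 0.0487 with pseudocount 0.1 and no filter; with all libraries, adjusted p = 0.700 with an estimated correlation). The chaperone genes Hspd1 (−0.87), Hspe1 (−0.82), Hsp90aa1 (−0.79) and Hsph1 (−0.63) fell and Dnajb9 rose (0.26), though not without shNS replicate 2, shNS replicate 3 or any 1 shTet1 library. Of 16 hypoxia response genes, Mxi1 (0.44) and Egln1 (0.41) rose and Pfkfb3 (−0.32) fell, and 0 passed adjusted over the list alone, with 5 at unadjusted p under 0.05 by limma and 7 by limma-voom. The list was not called (limma camera adjusted p = 0.157), but was with the replicate block (9 rises and 2 falls, 0.0188, and adjusted p = 0.671 with an estimated correlation), without both replicate 1 libraries (7 rises, 0.0461) and without shNS replicate 1 (5 rises, 0.028). None of the 3 held in every fit: Pfkfb3 was not past the test with median-of-ratios scaling, Mxi1 without shNS replicate 2 or shNS replicate 3, or Egln1 without shNS replicate 2, shNS replicate 3, shTet1 replicate 1 or shTet1 replicate 2.

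In all, 5 lists were called higher and 9 lower with the preset correlation, and 0 with the estimated one, where 2 lists had an unadjusted p under 0.05. Tested with fry in limma, 8 lists moved higher and 14 lower.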

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

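The fits without both replicate 1 libraries, without genes of identical reads, and by limma-voom with the replicate block, as well as the symbol families, were chosen after the data had been examined; the other alternatives were not. With group as the sole term, 2254 genes were higher and 3925 lower; leaving out 1 library gave 1698 to 2181 higher and 2676 to 4007 lower. Stricter thresholds gave fewer calls by construction. There were 1584 higher and 2470 lower at adjusted p under 0.01, and 539 higher and 355 lower with an absolute log2 change of at least 1. Among these larger changes, rises therefore outnumbered falls, unlike among all calls. Other settings gave 2692 and 4780 (replicate block), 3145 and 2994 (limma-voom), 3889 and 3872 (limma-voom with the block), 2457 and 4083 (no filter), and 1813 and 3255 (5 FPKM). Tet1 entered the test, and passed it, at −1.64 with limma-voom, −1.61 with limma-voom and the block, −0.35 without the filter and −1.24 with pseudocount 0.1 and no filter. Its 25 to 39 reads per shTet1 library limit its precision. Of the 31 lists tested, 5 were called higher and 9 lower, and limma camera with an estimated correlation called 0 (2 at unadjusted p under 0.05). Over the same 31 lists, 8 moved higher and 14 lower by fry, and 8 were called higher and 10 lower without both replicate 1 libraries. The replicate block called 3 further lists, the dendritic cell, hypoxia and ribosomal protein lists, and changed no other call of a list or named gene.

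Of 147 named genes tested, 139 had the same direction and call with median-of-ratios scaling, 140 with limma-voom, 147 with the block, without the filter or with pseudocount 0.1, and 137 to 143 without 1 library, where Vcan and Lck (without an shNS library) or Treml1, Ear6 and Cd22 (without an shTet1 library) fell below the filter. Tet3 turned from −0.04 to 0.088 with median-of-ratios scaling, 0.0925 with limma-voom and 0.0918 with limma-voom and the block, and ranged from −0.18 to 0.0888 without 1 library, above 0 without shNS replicate 2 or shTet1 replicate 1. Pbx3 turned from −0.07 to 0.0557, 0.0607 and 0.0626 in the first 3 of these. None passed the test in any of these. The megakaryocyte list turned from higher to lower, not called by limma camera: adjusted p 0.877 with median-of-ratios scaling, 0.919 with limma-voom, 0.914 without the filter, 0.475 with 5 FPKM, 0.879 with pseudocount 0.1 and no filter, 0.534 to 0.987 without 1 library (it stayed higher without shNS replicate 2) and 0.797 without both replicate 1 libraries; fry called it lower (0.00478). The T and NK cell list turned with limma-voom (0.685, and 0.769 with the block) and the fatty acid list with fry (0.392). The cause was not tested. The planned count models were not run, since the plan set limma on log2 values for a table of normalized values. Of the models run, only limma-voom used the recovered reads. Median-of-ratios scaling was applied to the FPKM values, and library size alone equals the deposited values.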

Other observations

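The tests of symbol families and of library scaling, admixed cells and culture oxygen were chosen only after the results were seen. Families of at least 5 tested genes that share a symbol stem were tested with limma camera as an exploratory screen, and 50 of 344 were called, 34 higher and 16 lower; with an estimated correlation 0 were called (12 at unadjusted p under 0.05), and fry called 235. Lysosomal cathepsins (Cts) had 11 rises and 1 fall among 14 genes (median 1.25, limma adjusted p 4.34e-05), with Ctsb from 83.7 ± 5.93 to 262 ± 36.2 FPKM, Ctsl from 83.7 ± 13 to 351 ± 77.9 FPKM, Ctss (2.16) and Ctsd (1.15) higher and Ctsw (−0.81) lower. C-type lectins (Clec) had 10 rises and 0 falls among 18 (median 0.97, limma adjusted p 9.01e-05), among them the beta-glucan receptor gene Clec7a, from 14.1 ± 2.36 to 68.2 ± 10.8 FPKM, Clec4d (1.78) and Clec4n (1.62). Toll-like receptors had 7 rises and 1 fall among 8 (median 1.15, limma adjusted p 0.000816), with the nucleic acid sensor gene Tlr7 from 3.28 ± 0.367 to 17.6 ± 3.62 FPKM, Tlr8 higher (1.87) and Tlr12 lower (−0.97). All 6 tested genes of colony-stimulating factors and their receptors (Csf) rose (median 1.02, limma adjusted p 0.00234), and 5 of them were in fixed lists. Klf transcription factors had 7 rises and 1 fall among 11 (median 0.65, limma adjusted p 0.0114), with Klf3 (1.36) and Klf13 (1.07) higher and Klf5 (−0.55) lower. Of the tested Klf and Cts genes, 3 and 2 were also in fixed lists.

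Among the families called lower, nucleoporins (Nup) had 18 falls and 0 rises among 20 genes (median −0.65, limma adjusted p 0.000936), with Nup85 from 44.3 ± 0.844 to 22.6 ± 3.96 FPKM and Nup43 at −1.03. All 10 tested genes of the stem Exosc, which encode subunits of the RNA exosome, fell (median −0.68, limma adjusted p 0.0108), with Exosc2 at −0.85. Proteins of the small mitochondrial ribosomal subunit (Mrps) had 21 falls and 0 rises among 29 (median −0.40, limma adjusted p 0.00634), and 14 falls and 1 rise with median-of-ratios scaling. All 7 tested genes of the stem Cct, which encode subunits of the chaperonin CCT, fell (median −0.59, limma adjusted p 0.0114), with Cct3 from 159.5 ± 5.34 to 86.8 ± 13.6 FPKM. These 9 families, named after their values were seen, kept their direction and call under each setting run except the estimated correlation.

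Of the 10 splits of the 6 libraries into 3 and 3, only the real one, 1 of 10, gave as many as 6179 calls by limma (6885 genes at unadjusted p under 0.05); the highest of the other splits gave 0, with between 10 and 519 genes at unadjusted p under 0.05. The 3 others that also part every same-numbered pair had 58, 18 and 23 such genes. Those splits are too few for a share under 0.05. Each of the other splits also mixes shNS and shTet1 libraries in its parts, so the difference between the groups widens the spread within a part. Their low counts therefore do not measure how many calls arise without a group difference.

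Monocyte and macrophage genes were higher and progenitor genes lower in shTet1. The monocyte median was at least 1.67 in each median-of-ratios fit, with all libraries or 1 left out. With all libraries, that scaling moved the all-gene median only from −0.13 to −0.01, too little to remove a rise of this size. The test could therefore not have failed, and it does not decide on scaling of the libraries as a cause. It shows only that the rise does not depend on the choice between the deposited and the median-of-ratios scaling. A minority of other cells added to the shTet1 libraries cannot lower a gene by more than 1 on the log2 scale. The progenitor median was at most −1.26 in the median-of-ratios fits, beyond that bound, which was set after the results were seen. The bound does not cover a minority of progenitor-rich cells in shNS that was lost in shTet1. A change in the mixture of cells is therefore not excluded. Each replicate number occurs once in each group, so a day shared by number is balanced between them. An effect of the loss of Tet1, off-target effects of the hairpin and the outgrowth of a subpopulation during selection stay open and were not tested.

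Interferon-stimulated genes were higher in shTet1, and 1 library alone does not account for it, since the list was called and its median was at least 0.83 with each library left out (with all libraries, adjusted p = 0.563 with an estimated correlation). Whether the rise is separate from that of the monocyte genes cannot be told apart with 3 shTet1 libraries. The mean log2 level of the monocyte list was 6.71, 6.77 and 6.42 in shTet1 replicates 1, 2 and 3 and that of the interferon list 3.43, 3.41 and 2.99, so replicate 3 was lowest in both (difference from the highest of the others for interferon −0.44). The rise may therefore be part of the same shift or a response of its own.

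Replicate 1 differed from replicates 2 and 3 in both groups: with group as a term, limma called 733 genes higher and 671 lower in it. The hypoxia list was higher there, with 12 of 16 genes higher (median 0.49, limma camera adjusted p 1.66e-10, adjusted p = 0.399 with an estimated correlation), with medians of 0.44 in shNS and 0.54 in shTet1 and the HIF target genes Ankrd37 (1.46), Ndrg1 (1.33) and Bnip3 (1.29) among them, while histone genes were lower (10 of 17, median −0.44, limma camera adjusted p 2.18e-10, adjusted p = 0.399 with an estimated correlation). By limma camera the MYC target (2.12e-07) and amino acid response (0.000228) lists were also lower in replicate 1 and the ribosomal protein (0.000118), glycolysis (0.00104), mast cell (0.00175), primary granule (0.0152) and immediate early (0.031) lists higher, each with adjusted p = 0.784 with an estimated correlation. Gene length is argued against by a Spearman correlation across genes of −0.044, and a bias with expression level, at −0.139, cannot be told apart, as that value lies between the bounds set for it. Lower oxygen or a denser culture of the replicate 1 cells may be the cause, as a hypothesis; the labels record no culture conditions per replicate.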
